A study of Homo sapiens with 30 samples.

How the data were processed

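RNA from SW1783 astrocytoma cells (ATCC HTB-13), grown in L-15 medium with fetal bovine serum, was collected 24 h after treatment, per the labels' protocols. Libraries were made from 1 µg of total RNA with an RNA integrity number above 7 using the MGIEasy RNA Directional kit, which marks strand, and sequenced on an MGIseq instrument as 100 bp paired-end reads. For extracts that inhibited growth by 20% below 500 µg/mL, the design text sets that inhibitory concentration as the highest dose, so doses are given as the sample labels state them. Water extracts and the positive control compounds that the design text names (wortmannin, LY294002 and thioridazine) were not analysed here.

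The authors deposited expected counts per gene, which are estimates that need not be whole. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with hg38 (GRCh38), and give these tools no order. The annotation release is not given in the sources used here. The table held 60675 Ensembl genes and 30 libraries, every column matched 1 sample of the series by its name, and 0 entries named no gene. Between 9.36 and 11.1% of the values of a library were not whole, and all were rounded to whole numbers before testing. Gene symbols were found for 56558 identifiers (93.2%), and unmatched identifiers took at most 0.15% of the counts of a library. Coordinates, GC content and lengths came from GENCODE v29 on GRCh38, which held 57055 of the identifiers. An expected count splits reads between near-identical genes by a model, so levels of SERPINB3 and SERPINB4, HSPA1A and HSPA1B, 7SK and 7SL copies, 18S copies and RGPD5 are uncertain. Replicate pairs differed by more than sampling noise, with mean chi-square values per gene of 2.56 to 37.5, so no pair was counted as 1 library deposited more than once. Such values do not tell separate cultures from repeated preparations of one RNA.

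Groups came from the sample labels. The samples, the comparisons, the tests, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. Genes with low counts were removed by edgeR's filterByExpr, leaving 19632, and libraries were scaled by TMM (edgeR 4.0.16, R 4.3.3). The filter goes by the smallest group, here 1 library, so enough counts in 1 library let a gene pass. A model of 13 group means over the 30 libraries was fitted with glmQLFit and tested with robust glmQLFTest, so that all groups shared the estimate of spread, with Benjamini-Hochberg adjustment per comparison at 0.05. The 15 planned comparisons set each dose of the 3 replicated formulas against vehicle, 500 against 20 µg/mL within each formula, and the formulas against each other at 500 µg/mL. Log2 CPM used a prior count of 2. Yijung-tang, with 1 library per dose, was part of the fit, where a group of 1 library adds nothing to the estimate of spread. It was described by log2 ratios to the vehicle mean and by whether a value lay outside the vehicle range. Its lists were described by the percentile of a list's median among 10000 random lists of the same size drawn from 50 expression bins. With the depth of 28.01 to 59.9 M counts, data of 19632 genes were simulated with the real means, library sizes and spread. Changes were given only to genes with a mean of at least 1 CPM, so recovery below that level was not measured. For Bojungikgi-tang at 500 µg/mL against vehicle, 58% of 1.25-fold, 94% of 1.5-fold and 100% of 2-fold changes were recovered, with 5.7% of calls false and 0 of wrong sign. For Banhasasim-tang at 500 µg/mL against vehicle these were 48, 88 and 96%, with 2.4% false.

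Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list. Adjustment ran over 306 tests (34 lists in 9 vehicle comparisons), over 204 in the 6 other comparisons and over 102 interaction tests, the last 2 families being chosen after the data were seen. At the preset correlation 97 of 306 tests passed, and 30 did with an estimated correlation. The lists, with at least 5 tested members each, covered ATF4 targets, NRF2 targets, endoplasmic reticulum chaperones, heat shock genes, cholesterol genes, fatty acid synthesis, LXR targets, G2/M, DNA replication, p53 targets, inflammatory cytokines, interferon response, hypoxia, glycolysis, metallothioneins and zinc genes, extracellular matrix, TGF-beta targets, matrix proteases, glucocorticoid targets, MAPK early genes, FOXO and PI3K feedback, autophagy and lysosome, nuclear oxidative phosphorylation, mitochondrially encoded messenger RNAs, cytosolic ribosomal proteins, ribosome biogenesis, histones, SRF targets, YAP targets, AhR targets, and markers of astrocytes, neurons, oligodendrocytes and epithelial or liver cells. A list of microglia and macrophage markers had 4 tested members and was not tested. Some lists share members, so their tests are not independent. For example, the ATF4 list shares SLC7A11 with the NRF2 list, SLC7A5 with the AhR list and SESN2 with the p53 list.

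Genes were named by a fixed rule. For each replicated formula at 500 µg/mL against vehicle these were the 12 highest and 12 lowest log2 fold changes among genes called, with at least 5 CPM in the higher group and every library of the one group beyond every library of the other, leaving out clone names and numbered pseudogenes. For the other comparisons the 5 highest and lowest were taken, for each list up to 4 members with the smallest p in the comparison with most called members, and for Yijung-tang the 10 highest and lowest outside the vehicle range at 500 µg/mL and on the same side at 100. Values of these genes in other comparisons are given for reference. Some genes that the rule selects are not reported here. Levels of cell identity markers and the mitochondrial and structural RNAs in single libraries were chosen for print after their values were seen.

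The other settings fixed beforehand were relative log expression factors, library size only, DESeq2 1.42.0, no filter on low counts, a filter of 5 CPM, only the 2 groups compared, the replicate number as a block, a threshold of 2-fold, the estimated correlation, and leaving out each replicate. Chosen after the data were seen were a loess correction for GC content and length (span 0.3), thinning to the shallowest library, 18S level as a covariate, removal of mitochondrial and structural RNA genes, and removal of 3 libraries that stood apart on the third principal component. Shared controls were weighed with 20 simulations of unchanged groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.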

Results

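Gene expression was measured by RNA sequencing in SW1783, an established human astrocytoma cell line, after 24 h of exposure to extracts of 4 multi-herb formulas of Korean traditional medicine. The series concerns digestive herbal medicine. Extracts made with 70% ethanol were given at 500, 100 and 20 µg/mL. Bojungikgi-tang and Sayeok-tang had 3 libraries at each dose, Banhasasim-tang had 2, and Yijung-tang had 1. Cells given vehicle had 3 libraries, labelled 0.1% DMSO, whereas the design text of the series gives 2%. Libraries held 28.01 to 59.9 M counts assigned to genes. These were 28.01 to 37.41 M in vehicle, 34.39 to 57.65 M in Bojungikgi-tang, 36.89 to 59.9 M in Sayeok-tang, 37.55 to 58.6 M in Banhasasim-tang and 39.34 to 46.66 M in Yijung-tang. The labels give no separate cultures, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2 scale, and expression levels are mean CPM with SD where a ± follows. Standard errors of single-gene fold changes were derived from the test. Each is the absolute fold change over the square root of the quasi-likelihood F statistic, so it is an approximation. Each gene named among the highest or lowest against vehicle at 500 µg/mL had all treated libraries beyond all vehicle libraries.

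The cells carried an incomplete astrocyte profile. In vehicle, the glutamate transporter SLC1A3 stood at 34.6 CPM, the gap junction gene GJA1 at 243 and the glial transcription factor SOX9 at 73.9, beside 0.0817 for the astrocyte filament gene GFAP, 0.211 for S100B and 0.339 for the glutamate transporter SLC1A2. Mesenchymal and epithelial filament genes were abundant, with 4280 CPM for VIM, 621 for KRT7 and 222 for KRT18. Markers of myeloid cells were low apart from the lysosomal gene CD68 at 141 CPM, with 13.8 CPM for PTPRC, 3.58 for CSF1R and 0.31 for CD14. Neuronal and oligodendrocyte genes were partly expressed, including TUBB3 at 106 CPM, SYT1 at 32.7 and CNP at 152.

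**Figure D1:**
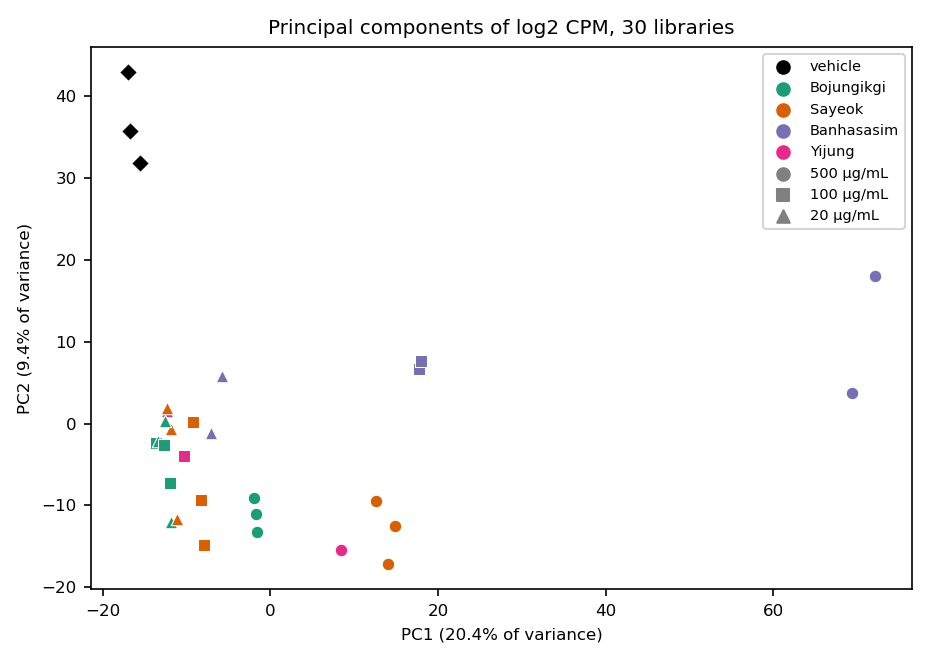
Principal components of log2 CPM, with the share of variance on each axis and 1 point per library, coloured by group. The 3 vehicle libraries lie at 31.82 to 43.02 on the second component (9.4% of the variance), above every treated library (18.09 or less), and the Banhasasim-tang 500 µg/mL libraries lie at 69.37 to 72.11 on the first (20.4%).

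The vehicle libraries stood apart from all treated libraries, including those at the lowest dose. At 20 µg/mL, 2733 genes differed from vehicle in the same direction for all 3 replicated formulas, 1280 higher and 1453 lower, and 1 gene went opposite ways. The genes higher in treated cells had a median GC content of 59% and a median length of 2630 bases, those lower 40.5% and 5355 bases, and all tested genes 48.3% and 2996 bases. Structural RNAs moved with this contrast: 18S ribosomal RNA loci took 108 to 330 CPM in vehicle and 226 to 3540 in treated libraries, and the 7SK RNA 0.6 to 2.97 against 2.76 to 31.1. Sample labels place vehicle in one label set (E1), Bojungikgi-tang and Sayeok-tang in another (15) and Banhasasim-tang and Yijung-tang in a further one (14). Treatment and label set therefore cannot be told apart in any comparison with vehicle, and the comparisons of 500 with 20 µg/mL, which hold no vehicle library, are given beside each.

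**Figure D2:**
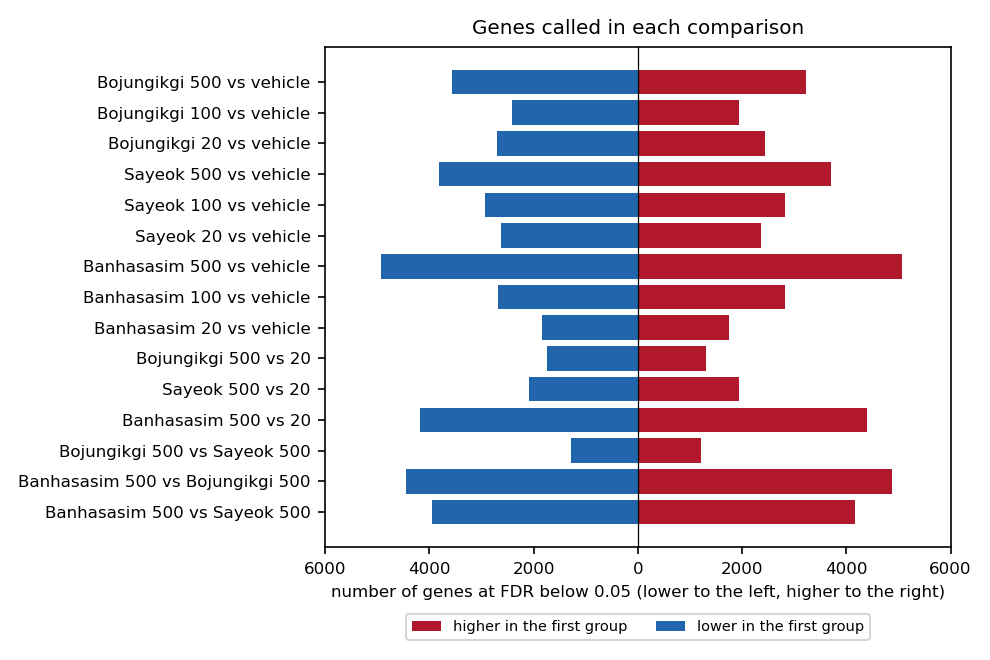
Number of genes higher (right, red) and lower (left, blue) at an adjusted p under 0.05 in edgeR's quasi-likelihood test, for the 15 comparisons. Counts run from 2484 for Bojungikgi-tang against Sayeok-tang to 10006 for Banhasasim-tang against vehicle, both at 500 µg/mL.

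Which genes differed between cells given Bojungikgi-tang and vehicle was asked at each dose. At 500 µg/mL, HMOX1, which degrades heme, rose by 1.95 ± 0.05 (227 ± 7.48 against 58.7 ± 0.598 CPM, n = 3 each), and the ferritin chains FTL and FTH1 rose by 1.57 ± 0.07 and 1.13 ± 0.08. The stress cytokine GDF15 rose by 1.53 ± 0.09 (12 ± 0.318 against 4.13 ± 0.218 CPM), the amino acid transporter SLC7A8 by 1.46 ± 0.08 and KYNU, an enzyme of tryptophan breakdown, by 1.12 ± 0.11. SERPINB3 and SERPINB4, near-identical protease inhibitors whose reads are uncertain, had values of 1.23 ± 0.15 and 1.24 ± 0.19. The oxytocin receptor OXTR had the most negative value of a well-measured gene, -1.80 ± 0.08 (6.11 against 21.4 CPM). It was followed by the phosphatase PTPRB at -1.46 ± 0.10, the guidance ligand SLIT2 at -1.29 ± 0.07 and the keratin KRT18 at -1.26 ± 0.05. Further down the named genes, the chemokine CCL2 stood at -1.09 ± 0.11. Adjusted p-values from edgeR were 1.14e-19 for HMOX1, 2.61e-13 for GDF15 and 3.47e-15 for OXTR. On GRCh38, HMOX1 lies on chromosome 22 at 35380361 to 35394214 (plus strand), GDF15 on chromosome 19 at 18374731 to 18389176 (plus strand) and OXTR on chromosome 3 at 8750408 to 8769628 (minus strand).

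Targets of NRF2, the transcription factor of the antioxidant response, rose as a group under Bojungikgi-tang at 500 µg/mL. Of 24 members, 19 rose and 0 fell over all genes, and 21 and 0 adjusted over the list alone (camera adjusted p = 4.61e-16, and adjusted p = 0.00862 with an estimated correlation). The cystine transporter SLC7A11 rose by 0.59 ± 0.09 over vehicle (211 against 140 CPM), and at 20 µg/mL it was at 104 CPM. ATF4 targets, which serve amino acid supply and the integrated stress response, had 20 of 25 members higher and 2 lower, and 20 and 2 adjusted over the list alone (adjusted p = 2.26e-12, and adjusted p = 0.00292 with an estimated correlation). Genes driven by SRF, the factor of the actin cytoskeleton, fell in 15 of 15, and 15 adjusted over the list alone (adjusted p = 7.04e-12, and adjusted p = 0.00292 with an estimated correlation). Among them ACTG1 stood at -0.63 ± 0.04 (2440 against 3760 CPM), ACTA2 at -0.75 ± 0.05 and VCL at -0.55 ± 0.05. YAP targets fell in 11 of 12 with 0 higher, and in 11 adjusted over the list alone (adjusted p = 3.07e-10, and adjusted p = 0.0101 with an estimated correlation). Cholesterol synthesis and uptake genes had 1 higher and 13 lower of 25, and 1 and 15 adjusted over the list alone (adjusted p = 3.74e-07, and adjusted p = 0.00966 with an estimated correlation). Ribosome biogenesis genes fell in 19 of 24 with 0 higher, and in 19 adjusted over the list alone (adjusted p = 2.05e-08, and adjusted p = 0.0136 with an estimated correlation). DKC1, of box H/ACA ribonucleoproteins, fell by 0.45 on the log2 scale (SE 0.03).

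Other lists were called under Bojungikgi-tang at 500 µg/mL at the preset correlation, and each call was lost with an estimated one. Extracellular matrix genes had 1 higher and 17 lower of 25, and 1 and 19 adjusted over the list alone (adjusted p = 1.7e-06, and adjusted p = 0.217 with an estimated correlation). G2/M genes had 1 higher and 14 lower of 25, and 1 and 16 adjusted over the list alone (adjusted p = 0.000166, and adjusted p = 0.218 with an estimated correlation). Autophagy and lysosome genes had 11 higher and 1 lower of 21, and 13 and 1 adjusted over the list alone (adjusted p = 0.000135, and adjusted p = 0.216 with an estimated correlation). FOXO and PI3K pathway genes had 8 higher and 1 lower of 15, and 8 and 1 adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.101 with an estimated correlation). Targets of the glucocorticoid receptor had 8 higher and 1 lower of 13, and 8 and 2 adjusted over the list alone (adjusted p = 0.0224, and adjusted p = 0.139 with an estimated correlation). Targets of the aryl hydrocarbon receptor had 5 higher and 1 lower of 9, and 5 and 1 adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.44 with an estimated correlation). Among these the xenobiotic-metabolising CYP1A1 stood at 1.18 ± 0.28 and CYP1B1 at 0.79 ± 0.14.

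Over all 19632 genes, edgeR called 3222 higher and 3569 lower for Bojungikgi-tang at 500 µg/mL, 1940 and 2408 at 100 and 2434 and 2705 at 20. With library size as the only scaling the split at 500 µg/mL was 3801 higher and 2832 lower. At 20 µg/mL the immediate early gene EGR1 rose by 0.94 ± 0.07 (37.4 against 19.5 CPM) and the RNA-binding SAMD4A fell by 0.80 ± 0.07 on the log2 scale. Neither was particular to this formula or dose. Across all treated groups EGR1 stood at 30.7 to 41.6 CPM, and SAMD4A at 16.4 to 30.8 against 36.4 in vehicle. At 100 µg/mL SAMD4A stood at -0.95 ± 0.07 and OXTR at -0.93 ± 0.08. With 18S level as a covariate, added after the data were seen, the counts at 100 and 20 µg/mL were 2264 and 2599, and with the 2 compared groups alone the count at 20 was 2758. Without vehicle, edgeR called 90 genes higher and 217 lower at 100 than at 20 µg/mL of Bojungikgi-tang, a comparison not among the planned ones.

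Whether the high dose differed from the low dose was asked without vehicle. Against 20 µg/mL of Bojungikgi-tang, 500 µg/mL raised HMOX1 by 1.90 ± 0.05, GDF15 by 1.48 ± 0.08, the anticoagulant receptor THBD by 1.02 ± 0.14 and ANGPTL4, an inhibitor of lipoprotein lipase, by 1.01 ± 0.07. OXTR stood at -1.47 ± 0.08, ANKRD1 at -1.33 ± 0.06 and the R-spondin receptor LGR6 at -1.14 ± 0.09. The YAP targets CCN1 and CCN2 were at 166 against 310 CPM and 54.6 against 105. In this contrast YAP targets fell in 12 of 12 members, also adjusted over the list alone (adjusted p = 2.62e-19, and adjusted p = 0.000303 with an estimated correlation), SRF targets in 15 of 15, also adjusted over the list alone (adjusted p = 2.61e-27, and adjusted p = 1.05e-05 with an estimated correlation) and ribosome biogenesis genes in 18 of 24, and 18 adjusted over the list alone (adjusted p = 5.61e-12, and adjusted p = 0.00178 with an estimated correlation). NRF2 targets rose in 20 of 24, and 21 adjusted over the list alone (adjusted p = 2.7e-30, and adjusted p = 0.000223 with an estimated correlation). ATF4 targets had 17 of 25 higher and 1 lower, and 20 and 1 adjusted over the list alone (adjusted p = 1.85e-21, and adjusted p = 4.55e-05 with an estimated correlation). TGF-beta targets had 0 higher and 7 lower of 16, and 1 and 8 adjusted over the list alone (adjusted p = 4.34e-07, and adjusted p = 0.00433 with an estimated correlation).

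In all, 1304 genes were higher and 1747 lower at 500 than at 20 µg/mL of Bojungikgi-tang. Of the 6791 genes called against vehicle at 500 µg/mL, 2124 (31.3%) were called in the same direction against 20 µg/mL and 43 in the opposite one. Both contrasts hold the same 500 µg/mL libraries, which by itself favours agreement in direction. Of the 6791 genes, 3628 were also called the same way at 20 µg/mL against the same vehicle libraries. With library size as the only scaling the split between the doses was 2329 higher and 1023 lower, and with the 2 compared groups alone 1336 genes passed.

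**Figure D3:**
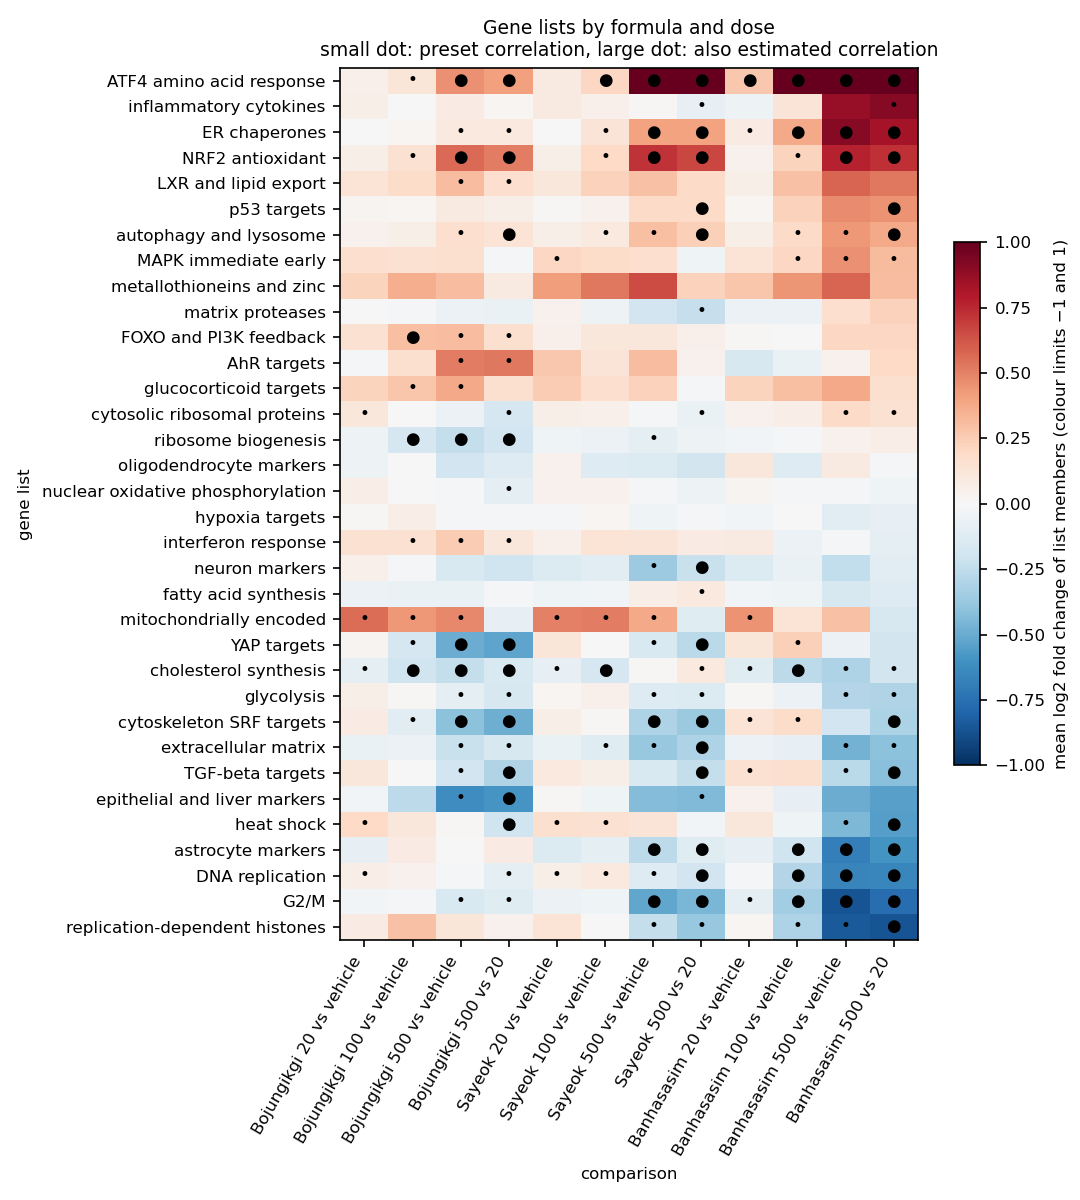
Mean log2 fold change of each gene list (rows) at 20, 100 and 500 µg/mL against vehicle and at 500 against 20 µg/mL for each replicated formula (columns), with colour from -1 to 1, a small dot for a camera call at the preset correlation and a large dot for one that also held with an estimated correlation. ATF4 targets reached a mean of 2.16 under Banhasasim-tang at 500 µg/mL against 1.11 under Sayeok-tang and 0.46 under Bojungikgi-tang.

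Sayeok-tang at 500 µg/mL was compared with vehicle in the same way. GDF15 rose by 3.09 ± 0.08 (35.4 ± 3.47 against 4.13 ± 0.218 CPM) and HMOX1 by 2.76 ± 0.06 (398 ± 20.9 against 58.7 ± 0.598 CPM), with adjusted p-values of 4.6e-21 and 2.16e-23 from edgeR, n = 3 each. CHAC1, which breaks down glutathione, rose by 2.37 ± 0.10, the peptide hormone gene ADM2 by 2.31 ± 0.13, the calcium pump ATP2A3 by 2.33 ± 0.13, the transsulfuration enzyme CBS by 1.95 ± 0.07 and the stress regulator NUPR1 by 1.84 ± 0.09. The hyaluronan synthase HAS2 stood at -1.46 ± 0.06 (27.7 against 76.1 CPM) and CEMIP, which degrades hyaluronan, at -1.39 ± 0.10. TNFSF15, a cytokine of the tumour necrosis factor family, stood at -1.75 ± 0.12, CCL2 at -1.60 ± 0.12 (7.89 against 24.1 CPM) and the hedgehog inhibitor HHIP at -1.40 ± 0.11.

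Under Sayeok-tang at 500 µg/mL, G2/M genes fell in 25 of 25, and in 25 adjusted over the list alone (adjusted p = 1.92e-22, and adjusted p = 0.00303 with an estimated correlation). The mitotic kinesin KIF20A stood at -0.84 ± 0.04 (56.9 against 102 CPM), DLGAP5 at -0.71 ± 0.04 and the kinase AURKA at -0.54 ± 0.04. ATF4 targets rose in 23 of 25 with 0 lower, and 23 and 1 adjusted over the list alone (adjusted p = 2.44e-27, and adjusted p = 3.24e-05 with an estimated correlation). NRF2 targets rose in 22 of 24 with 0 lower, and in 22 adjusted over the list alone (adjusted p = 1.74e-18, and adjusted p = 0.00546 with an estimated correlation). Among these the quinone reductase NQO1 stood at 1.11 ± 0.05. Chaperones of the endoplasmic reticulum rose in 14 of 18 with 0 lower, and in 14 adjusted over the list alone (adjusted p = 4.68e-10, and adjusted p = 0.0136 with an estimated correlation). SRF targets fell in 12 of 15, and in 12 adjusted over the list alone (adjusted p = 7.78e-07, and adjusted p = 0.0134 with an estimated correlation). Astrocyte markers fell in 7 of 11, and in 7 adjusted over the list alone (adjusted p = 0.00241, and adjusted p = 0.0438 with an estimated correlation), with SLC1A3 at -0.58. Extracellular matrix genes had 1 higher and 23 lower of 25, and 1 and 23 adjusted over the list alone (adjusted p = 1.91e-11, and adjusted p = 0.0654 with an estimated correlation). The collagens COL3A1 and COL1A1 stood at -0.83 ± 0.05 and -0.41 ± 0.04 (2490 against 3320 CPM).

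Over all genes, 3699 were higher and 3815 lower than vehicle for Sayeok-tang at 500 µg/mL, 2814 and 2928 at 100 and 2352 and 2621 at 20. With library size as the only scaling the split at 500 µg/mL was 4116 higher and 3318 lower. EGR1 rose by 0.94 ± 0.07 at 100 µg/mL, where the interferon gene IFNE stood at -0.88 ± 0.10 and SAMD4A at -0.85 ± 0.07, and SAMD4A stood at -0.73 ± 0.07 at 20 µg/mL. In every treated group of all formulas, EGR1 lay above the vehicle mean and IFNE and SAMD4A below it. At 100 µg/mL ATF4 targets had 15 of 25 higher and 1 lower, and 16 and 3 adjusted over the list alone (adjusted p = 2.84e-05, and adjusted p = 0.0438 with an estimated correlation). With 18S level as a covariate the count at 20 µg/mL was 2950. Without vehicle, edgeR called only 4 genes higher and 2 lower at 100 than at 20 µg/mL of Sayeok-tang, a comparison not among the planned ones.

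Between the doses of Sayeok-tang, 500 against 20 µg/mL, HMOX1 rose by 2.78 ± 0.06, GDF15 by 2.69 ± 0.07, ADM2 by 2.19 ± 0.11 and CHAC1 by 1.80 ± 0.09. CCL2 stood at -1.5 ± 0.12, TNFSF15 at -1.48 ± 0.12 and LGR6 at -1.43 ± 0.09. ATF4 targets had 24 of 25 higher and 1 lower, also adjusted over the list alone (adjusted p = 1.55e-46), G2/M genes fell in 25 of 25, also adjusted over the list alone (adjusted p = 2.64e-35, and adjusted p = 8.89e-05 with an estimated correlation) and endoplasmic reticulum chaperones rose in 18 of 18, also adjusted over the list alone (adjusted p = 1.85e-21, and adjusted p = 0.000264 with an estimated correlation). DNA replication genes fell in 18 of 26, and in 20 adjusted over the list alone (adjusted p = 1.36e-11, and adjusted p = 0.0388 with an estimated correlation), whereas against vehicle 14 fell and 3 rose, and 14 and 4 adjusted over the list alone (adjusted p = 0.00417, and adjusted p = 0.444 with an estimated correlation). Extracellular matrix genes fell in 18 of 25, and in 22 adjusted over the list alone (adjusted p = 8.27e-17, and adjusted p = 0.0121 with an estimated correlation). YAP targets fell in 9 of 12, and in 10 adjusted over the list alone (adjusted p = 4.24e-07, and adjusted p = 0.0187 with an estimated correlation). Autophagy and lysosome genes rose in 13 of 21 with 0 lower, and in 13 adjusted over the list alone (adjusted p = 1.14e-10, and adjusted p = 0.013 with an estimated correlation).

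In this contrast 1942 genes were higher and 2089 lower. Of the 7514 genes called against vehicle at 500 µg/mL of Sayeok-tang, 2907 (38.7%) were called in the same direction against 20 µg/mL and 49 in the opposite one. The shared 500 µg/mL libraries favour such agreement. At 20 µg/mL against the same vehicle libraries, 3580 of the 7514 were also called the same way. With library size as the only scaling, 2639 were higher and 1563 lower at 500 than at 20 µg/mL.

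Banhasasim-tang at 500 µg/mL, compared with vehicle, had the largest fold changes of the replicated formulas (n = 2 against 3). GDF15 rose by 6.01 ± 0.08, from 4.13 ± 0.218 to 266 ± 26.1 CPM, with an adjusted p of 2.48e-28 from edgeR. KCP, a secreted chordin-like protein, rose by 5.46 ± 0.18 (18.7 against 0.441 CPM) and the mitochondrial ribosomal RNA MT-RNR1 by 4.59 ± 0.19 (16800 against 701 CPM). The neurotrophin receptor NGFR rose by 4.4 ± 0.14 (25.3 against 1.19 CPM), the hexokinase HKDC1 by 4.39 ± 0.11 and the lysosomal membrane gene LAMP3 by 4.36 ± 0.23. ADM2 rose by 4.29 ± 0.12, the pseudokinase TRIB3 by 3.86 ± 0.06 (286 against 19.8 CPM) and the stress transcription factors ATF3 and DDIT3 by 3.78 ± 0.13 and 3.65 ± 0.08. LGR6 stood at -3.06 ± 0.14, the integrin ITGB8 at -2.70 ± 0.10 (13.9 against 89.9 CPM), the exchange factor VAV3 at -2.55 ± 0.09, the deiodinase DIO2 at -2.41 ± 0.07 and the growth factor FGF7 at -2.24 ± 0.08. The glutamate transporter SLC1A3 was at 7.93 against 34.6 CPM, a value of -2.12 ± 0.07 with an adjusted p of 3.78e-20 from edgeR.

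**Figure D4:**
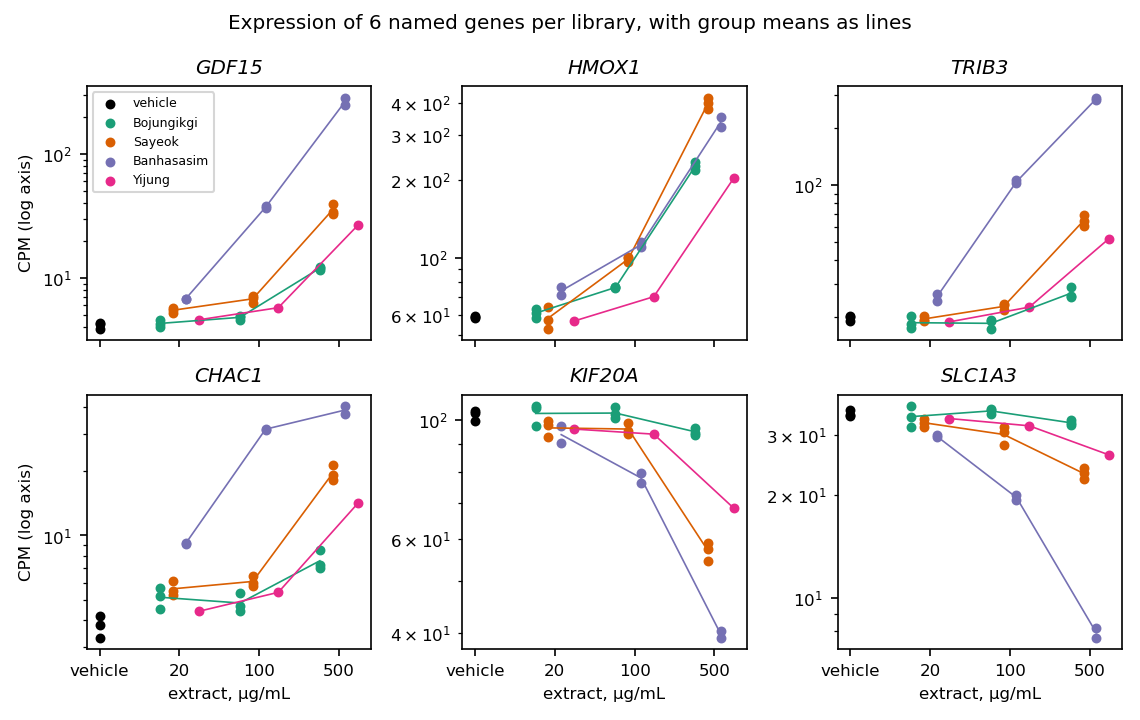
CPM per library (log axis) of 6 genes against dose in µg/mL, with vehicle at the left, points shifted sideways by formula and lines through the group means. GDF15 averaged 266 CPM under Banhasasim-tang at 500 µg/mL, 35.4 under Sayeok-tang and 12 under Bojungikgi-tang, against 4.13 in vehicle.

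All 25 ATF4 targets rose under Banhasasim-tang at 500 µg/mL, and all 25 adjusted over the list alone (adjusted p = 7.4e-27, and adjusted p = 3.24e-05 with an estimated correlation). SESN2 stood at 2.43 ± 0.05 and the alanine tRNA synthetase AARS1 at 1.63 ± 0.04. Endoplasmic reticulum chaperones rose in 18 of 18, and in 18 adjusted over the list alone (adjusted p = 9.32e-14, and adjusted p = 0.00546 with an estimated correlation). HSPA5, the main chaperone of that compartment, was at 14000 against 3570 CPM (1.97 ± 0.05). NRF2 targets had 20 of 24 higher and 2 lower, and 20 and 2 adjusted over the list alone (adjusted p = 1.87e-09, and adjusted p = 0.0465 with an estimated correlation). G2/M genes fell in 25 of 25, and in 25 adjusted over the list alone (adjusted p = 1.78e-19, and adjusted p = 0.00546 with an estimated correlation). DNA replication genes had 1 higher and 23 lower of 26, and 1 and 23 adjusted over the list alone (adjusted p = 5.34e-14, and adjusted p = 0.0491 with an estimated correlation). Astrocyte markers had 1 higher and 7 lower of 11, and 1 and 7 adjusted over the list alone (adjusted p = 0.00206, and adjusted p = 0.0421 with an estimated correlation). Beside SLC1A3, GJA1 stood at -0.67 ± 0.04 and SOX9 at -0.56 ± 0.05.

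Further lists were called under Banhasasim-tang at 500 µg/mL at the preset correlation alone. Heat shock genes fell in 13 of 17, and in 13 adjusted over the list alone (adjusted p = 5.44e-06, and adjusted p = 0.101 with an estimated correlation). Cholesterol synthesis and uptake genes had 2 higher and 15 lower of 25, and 2 and 15 adjusted over the list alone (adjusted p = 0.000295, and adjusted p = 0.0561 with an estimated correlation). Extracellular matrix genes had 2 higher and 19 lower of 25, and 2 and 21 adjusted over the list alone (adjusted p = 2.84e-06, and adjusted p = 0.218 with an estimated correlation). Autophagy and lysosome genes had 17 higher and 2 lower of 21, and 17 and 2 adjusted over the list alone (adjusted p = 1.43e-06, and adjusted p = 0.101 with an estimated correlation). The autophagy receptor SQSTM1 stood at 1.58 ± 0.05. MAPK feedback and early genes had 13 higher and 5 lower of 21, and 13 and 5 adjusted over the list alone (adjusted p = 0.00255, and adjusted p = 0.348 with an estimated correlation). The phosphatase DUSP5 stood at 2.06 ± 0.06. Glycolysis genes had 3 higher and 13 lower of 18, and 3 and 13 adjusted over the list alone (adjusted p = 0.00521, and adjusted p = 0.391 with an estimated correlation), with LDHA at -1.07 ± 0.06. Histone genes fell in 9 of 13, and in 10 adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.124 with an estimated correlation). SRF targets had 2 higher and 7 lower of 15, and 2 and 7 adjusted over the list alone, which was not called (adjusted p = 0.0849, or 0.0176 with library size as the only scaling).

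At 100 µg/mL of Banhasasim-tang, GDF15 rose by 3.16 ± 0.08, ADM2 by 3.10 ± 0.13 and CHAC1 by 3.07 ± 0.10, and TXNIP, which binds thioredoxin, stood at -2.03 ± 0.13. ATF4 targets rose in 25 of 25, and in 25 adjusted over the list alone (adjusted p = 4.93e-44, and adjusted p = 2.69e-06 with an estimated correlation). G2/M genes fell in 23 of 25, and in 25 adjusted over the list alone (adjusted p = 4.66e-18, and adjusted p = 0.00546 with an estimated correlation). At 20 µg/mL, ATF4 targets had 16 of 25 higher and 2 lower, and 18 and 2 adjusted over the list alone (adjusted p = 2.02e-09, and adjusted p = 0.00546 with an estimated correlation), with CHAC1 at 1.29 ± 0.11 and TXNIP at -0.97 ± 0.12. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 were higher at every dose of this formula, with MT-RNR2 at 2.91 ± 0.06, 3.32 ± 0.07 and 1.89 ± 0.06 at 500, 100 and 20 µg/mL. MT-RNR2 took 3.02 to 8.19% of the counts of the Banhasasim-tang libraries and 0.87 to 0.93% of those of vehicle.

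**Figure D5:**
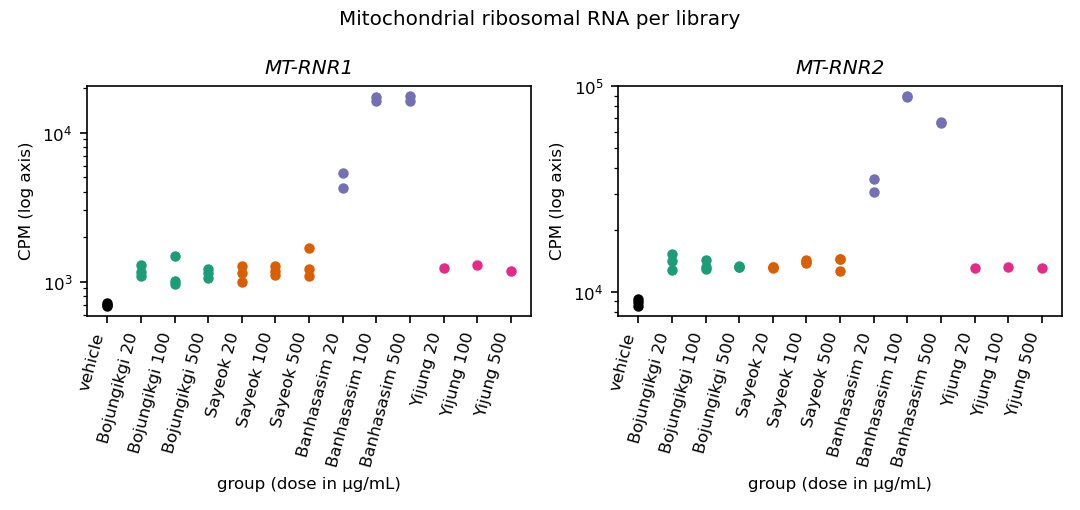
CPM per library (log axis) of the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 in each group. The lowest Banhasasim-tang library held 4250 CPM of MT-RNR1 and the highest Yijung-tang library 1280.

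Over all genes, 5075 were higher and 4931 lower than vehicle under Banhasasim-tang at 500 µg/mL, 2819 and 2690 at 100 and 1746 and 1843 at 20. With library size as the only scaling the splits were 3507 and 6775, 1278 and 6229, and 1107 and 3088, with the median of all genes moved by -0.129 and -0.149 at 500 and 100 µg/mL, a scaling in which the mitochondrial ribosomal RNAs take part of each total. Leaving out replicate 2 at 100 µg/mL gave 3288 genes. At 20 µg/mL, 1183 genes passed without replicate 2, 2145 without replicate 3, 2256 without vehicle replicate 1 and 5603 with the 2 compared groups alone.

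Against 20 µg/mL of the same formula, Banhasasim-tang at 500 µg/mL raised GDF15 by 5.29 ± 0.08, LAMP3 by 4.69 ± 0.25, HKDC1 by 4.23 ± 0.12 and ATF3 by 3.89 ± 0.14. The stromal membrane gene CD248 stood at -3.56 ± 0.17, LGR6 at -2.89 ± 0.15 and the prolyl hydroxylase EGLN3 at -2.40 ± 0.14. ATF4 targets rose in 25 of 25, also adjusted over the list alone (adjusted p = 2.58e-31), endoplasmic reticulum chaperones in 18 of 18, also adjusted over the list alone (adjusted p = 5.63e-16, and adjusted p = 0.00121 with an estimated correlation), and G2/M genes fell in 25 of 25, also adjusted over the list alone (adjusted p = 8.65e-22, and adjusted p = 0.000973 with an estimated correlation). DNA replication genes fell in 25 of 26, and in 25 adjusted over the list alone (adjusted p = 1.55e-18, and adjusted p = 0.012 with an estimated correlation). Heat shock genes had 1 higher and 13 lower of 17, and 1 and 13 adjusted over the list alone (adjusted p = 1.09e-07, and adjusted p = 0.0251 with an estimated correlation). TGF-beta targets had 1 higher and 13 lower of 16, and 2 and 13 adjusted over the list alone (adjusted p = 4.51e-05, and adjusted p = 0.0148 with an estimated correlation), with the feedback gene PMEPA1 at -0.86 ± 0.04. Targets of p53 had 9 higher and 5 lower of 21, and 10 and 5 adjusted over the list alone (adjusted p = 0.00779, and adjusted p = 0.0249 with an estimated correlation). This list shares SESN2 with that of ATF4 targets, so it is not fully separate evidence. Astrocyte markers fell in 7 of 11, and in 7 adjusted over the list alone (adjusted p = 0.000666, and adjusted p = 0.0141 with an estimated correlation).

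Between these doses 4387 genes were higher and 4185 lower, or 3359 and 5184 with library size as the only scaling. Of the 10006 genes called against vehicle at 500 µg/mL, 7078 (70.7%) were called in the same direction against 20 µg/mL and 30 in the opposite one. Here too the shared 500 µg/mL libraries favour agreement. At 20 µg/mL against the same vehicle libraries, 2288 of the 10006 were also called the same way. At 100 against 20 µg/mL of Banhasasim-tang, a comparison not among the planned ones, 714 genes were higher and 582 lower.

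The formulas were compared with each other at 500 µg/mL. Bojungikgi-tang and Sayeok-tang, which share a label set, differed in 2484 genes, 1201 higher and 1283 lower in Bojungikgi-tang. SERPINB3 was higher by 1.69 ± 0.15, the cytokine IL11 by 1.13 ± 0.05 and TXNIP by 1.08 ± 0.10 in Bojungikgi-tang, and GDF15 stood at -1.56 ± 0.06, ADM2 at -1.53 ± 0.11 and TRIB3 at -1.27 ± 0.06. G2/M genes were higher in 25 of 25, also adjusted over the list alone (adjusted p = 1.86e-39, and adjusted p = 4.77e-05 with an estimated correlation). ATF4 targets were lower in 22 of 25, and in 22 adjusted over the list alone (adjusted p = 5.08e-44, and adjusted p = 9.72e-07 with an estimated correlation). Cholesterol genes were lower in 16 of 25, and in 20 adjusted over the list alone (adjusted p = 2.31e-19, and adjusted p = 4.55e-05 with an estimated correlation). Under Sayeok-tang against vehicle 8 were higher and 5 lower, and 8 and 5 adjusted over the list alone (adjusted p = 0.874). YAP targets had 1 higher and 8 lower of 12, and 2 and 10 adjusted over the list alone (adjusted p = 8.59e-10, and adjusted p = 0.00711 with an estimated correlation). Ribosome biogenesis genes were lower in 13 of 24, and in 14 adjusted over the list alone (adjusted p = 8.98e-09, and adjusted p = 0.00711 with an estimated correlation).

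Banhasasim-tang at 500 µg/mL had 4883 genes higher and 4445 lower than Bojungikgi-tang and 4157 higher and 3944 lower than Sayeok-tang. GDF15 was higher by 4.47 ± 0.07 and HKDC1 by 4.14 ± 0.10 than under Bojungikgi-tang, and HKDC1 by 3.04 ± 0.09 and NGFR by 3.02 ± 0.12 than under Sayeok-tang. CD248 stood at -3.67 ± 0.16 and VAV3 at -2.66 ± 0.09 against Bojungikgi-tang, and ITGB8 at -1.92 ± 0.10 against Sayeok-tang. ATF4 targets were higher in 25 of 25 than under either formula, also adjusted over the list alone (adjusted p = 2.61e-27 against Bojungikgi-tang and 1.62e-23 against Sayeok-tang, and adjusted p = 1.35e-05 and 3.19e-05 with an estimated correlation). Inflammatory cytokine genes were higher in 12 of 21 and lower in 2 than under Sayeok-tang, and 13 and 3 adjusted over the list alone (adjusted p = 0.00014, and adjusted p = 0.0251 with an estimated correlation). Against Bojungikgi-tang the list had 13 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.115 with an estimated correlation). In that comparison IL6 stood at 1.37 ± 0.09, CXCL8 at 1.60 ± 0.12 and IL11 at -1.70 ± 0.06. Against vehicle the same list had 12 higher and 4 lower, and 12 and 4 adjusted over the list alone, and was not called (adjusted p = 0.0704, or 0.0184 with library size as the only scaling). Heat shock genes were lower in 13 of 17 with 0 higher than under Sayeok-tang, and 13 and 1 adjusted over the list alone (adjusted p = 1.49e-08, and adjusted p = 0.0187 with an estimated correlation). Against Bojungikgi-tang they had 3 higher and 12 lower, and 3 and 13 adjusted over the list alone (adjusted p = 8.77e-06, and adjusted p = 0.0542 with an estimated correlation), with HSPA8 at -1.05 ± 0.04. DNA replication genes were lower in 24 of 26 than under Sayeok-tang, and in 25 adjusted over the list alone (adjusted p = 9.35e-19, and adjusted p = 0.0118 with an estimated correlation). Against Bojungikgi-tang they had 1 higher and 25 lower, also adjusted over the list alone (adjusted p = 1.69e-17, and adjusted p = 0.013 with an estimated correlation). There UHRF1, of DNA methylation maintenance, and the ribonucleotide reductase subunit RRM2 stood at -1.18 ± 0.05 and -1.16 ± 0.05. Banhasasim-tang lies in another label set than both, and across the same sets 30 and 26 genes were called at 20 µg/mL. With library size as the only scaling the splits were 2745 and 7095 against Bojungikgi-tang and 2209 and 6712 against Sayeok-tang, and the median of all genes moved by -0.163 and -0.152.

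Differences between formulas in their own 500 over 20 µg/mL change, tested as interactions chosen after the data were seen, hold no vehicle library and no comparison across label sets at a single dose. For ATF4 targets the change was larger under Sayeok-tang than under Bojungikgi-tang in 22 of 25 genes (mean difference 0.61, adjusted p = 1.33e-47, and adjusted p = 5.44e-07 with an estimated correlation). It was larger under Banhasasim-tang than under Sayeok-tang in 21 of 25 (mean difference 0.86, adjusted p = 1.34e-22, and adjusted p = 4.05e-05 with an estimated correlation). For G2/M genes the change was lower under Sayeok-tang than under Bojungikgi-tang in 21 of 25 (adjusted p = 3.7e-37, and adjusted p = 6.43e-05 with an estimated correlation) and lower under Banhasasim-tang than under Sayeok-tang in 18 of 25 (adjusted p = 1.2e-09, and adjusted p = 0.0223 with an estimated correlation). Cholesterol genes had a higher change under Sayeok-tang than under Bojungikgi-tang in 14 of 25 (adjusted p = 1.76e-18, and adjusted p = 5.77e-05 with an estimated correlation). Under Banhasasim-tang their change was lower than under Sayeok-tang in 12 of 25 (mean difference -0.28, adjusted p = 3.6e-07, and adjusted p = 0.00643 with an estimated correlation). YAP targets had a higher change under Sayeok-tang than under Bojungikgi-tang in 5 of 12 (adjusted p = 1.03e-06, and adjusted p = 0.0237 with an estimated correlation). At 20 µg/mL edgeR called 0 genes between Sayeok-tang and Bojungikgi-tang, with 720 at an unadjusted p under 0.05, and DESeq2 called 0, with 403. Banhasasim-tang at that dose differed in 30 genes from Bojungikgi-tang and in 26 from Sayeok-tang.

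Calls of the formulas at 500 µg/mL against vehicle overlapped. Bojungikgi-tang and Sayeok-tang shared 2440 higher and 2653 lower genes, where independent lists would share 607 and 694, and 63 genes went opposite ways. Sayeok-tang and Banhasasim-tang shared 2570 and 2559, against 956 and 958, with 453 opposite, and Bojungikgi-tang and Banhasasim-tang 1889 and 2019, against 833 and 896, with 887 opposite. Across genes, which are not independent replicates, fold changes correlated at 0.72, 0.62 and 0.50 in that order, where simulated groups without effects against the same vehicle libraries gave 0.59, 0.49 and 0.50. Covariances were 0.235, 0.309 and 0.232 against simulated values of 0.0818, 0.0795 and 0.0795. Over the 11292 genes with a mean of at least 5 CPM, covariances were 0.0625, 0.0996 and 0.0579 against simulated values of 0.00321, 0.00325 and 0.00315. Correlations over these genes were 0.84, 0.70 and 0.46 against simulated values of 0.54, 0.48 and 0.47. The 3 vehicle libraries cannot be split so that each part keeps 2, so part of the excess may come from the shared controls. At 20 µg/mL against vehicle, Bojungikgi-tang and Sayeok-tang already shared 1848 higher and 2188 lower genes, with 0 opposite. Correlations at that dose were 0.74, 0.67 and 0.68 in the same order of pairs. Over genes with a mean of at least 5 CPM they were 0.95, 0.90 and 0.90, above those at 500 µg/mL. Overlap against vehicle therefore cannot be read as a likeness that belongs to the high dose. In the contrasts of 500 with 20 µg/mL, which share no library, Bojungikgi-tang and Sayeok-tang shared 685 higher and 952 lower genes (129 and 186 for independent lists), with 57 opposite and a correlation of 0.20. Sayeok-tang and Banhasasim-tang shared 1359 and 1533 (434 and 445), with 174 opposite and a correlation of 0.31. Bojungikgi-tang and Banhasasim-tang shared 683 and 949 (291 and 372), with 434 opposite and a correlation of 0.15. These last correlations were 0.63, 0.68 and 0.36 over the 11292 genes with a mean of at least 5 CPM.

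Yijung-tang had 1 library per dose, so no test was made and its differences have no replicate check. At 500 µg/mL the log2 ratio to the vehicle mean was 2.69 for GDF15 (26.7 CPM), 1.92 for CHAC1, 1.90 for FTL, 1.87 for ADM2, 1.79 for HMOX1 (203 CPM), 1.72 for CBS and 1.67 for NUPR1. GDF15 stood at 0.48 and 0.15 at 100 and 20 µg/mL and HMOX1 at 0.26 and -0.05. Among the lowest at 500 µg/mL were TNFSF15 at -1.48, CEMIP at -1.41, OXTR at -1.30, LGR6 at -1.29, SLIT2 at -1.26 and HAS2 at -1.25. The median of ATF4 targets was 0.90, at percentile 100 among 10000 random lists matched on expression, with 23 of 25 members above every vehicle library. NRF2 targets had a median of 0.51 (percentile 100), endoplasmic reticulum chaperones 0.42 (percentile 100), G2/M genes -0.37 (percentile 0, with 23 of 25 below every vehicle library) and YAP targets -0.45 (percentile 0). As ratios of the 500 to the 20 µg/mL library these medians were 0.79, 0.56, 0.32, -0.31 and -0.44. Over 11292 genes these ratios correlated at 0.68 with the 500 over 20 µg/mL fold changes of Sayeok-tang, 0.52 with those of Banhasasim-tang and 0.47 with those of Bojungikgi-tang. Of the genes called between doses, 2942 of 3248 (90.6%) for Sayeok-tang, 2057 of 2545 (80.8%) for Bojungikgi-tang and 4624 of 6507 (71.1%) for Banhasasim-tang had a Yijung-tang ratio in the same direction.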

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

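The interaction tests, of differences between formulas in their change from 20 to 500 µg/mL, were chosen only after the data were seen. The change from 20 to 500 µg/mL differed between Banhasasim-tang and Bojungikgi-tang in 6237 genes by edgeR's interaction test, of which 434 were called in opposite directions in the 2 formulas. Among genes with a mean of at least 5 CPM over all libraries, the highest and lowest differences were 4.12 ± 0.17 for HKDC1, a hexokinase (4.23 under Banhasasim-tang and 0.11 under Bojungikgi-tang, adjusted p = 1.76e-16), and -3.51 ± 0.20 for CD248, a stromal membrane protein (-3.56 and -0.05, adjusted p = 7.51e-14). Between Banhasasim-tang and Sayeok-tang 4791 genes differed, 174 of them called in opposite directions, with the highest and lowest differences under the same limit being 3.00 ± 0.16 for HKDC1 (4.23 and 1.23, adjusted p = 1.63e-13) and -2.61 ± 0.21 for CD248 (-3.56 and -0.94, adjusted p = 1.82e-10).

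Sayeok-tang and Bojungikgi-tang differed in this change in 882 genes, with 57 called in opposite directions. Under that limit the peptide hormone gene ADM2 differed by 1.63 ± 0.17 (2.19 under Sayeok-tang and 0.56 under Bojungikgi-tang, adjusted p = 4.96e-07) and SERPINB3 by -1.47 ± 0.21 (-0.67 and 0.81, adjusted p = 8.25e-05). Reads of SERPINB3 are shared with its near-identical neighbour SERPINB4.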

How the results depend on the processing

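Added after the data were seen were GC and length correction, thinning, the 18S covariate, removal of mitochondrial and structural RNA genes or of 3 libraries, and all alternatives for the comparison of formulas. In the 15 comparisons, relative log expression factors, library size only, DESeq2, no filter, the 5 CPM filter, GC and length correction, thinning and both removals kept each count of called genes within 1.5 times. Requiring a 2-fold change, which asks for more, left 377, 160 and 151 genes for Bojungikgi-tang at 500, 100 and 20 µg/mL against vehicle, 560, 181 and 165 for Sayeok-tang, and 1920, 335 and 104 for Banhasasim-tang. It left 104, 190 and 1418 between 500 and 20 µg/mL of these formulas, and 84, 1451 and 986 for Bojungikgi-tang against Sayeok-tang, Banhasasim-tang against Bojungikgi-tang and Banhasasim-tang against Sayeok-tang. The 18S covariate gave 2264 and 2599 genes for Bojungikgi-tang at 100 and 20 µg/mL and 2950 for Sayeok-tang at 20. With the 2 compared groups alone, 2758 genes passed for Bojungikgi-tang at 20 µg/mL against 5139 in the main fit, and 1336 against 3051 between its doses. Counts rose for Banhasasim-tang at 20 µg/mL, from 3589 to 5603, and for Bojungikgi-tang at 500 µg/mL, from 6791 to 8378. Bojungikgi-tang at 20 µg/mL held the replicate pairs with the largest mean chi-square values per gene, 36.88 and 37.5. Leaving out single libraries gave 3288 (without Banhasasim-tang replicate 2) to 4966 genes (without vehicle replicate 3) for Banhasasim-tang at 100 µg/mL, and 1183 to 3180 at 20, where the lone library left is assumed to vary like the other groups.

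Of 306 list tests 97 passed, 30 with an estimated correlation and 91 with library size only, which turned no called list. Of 320 values of named genes, library size only ended 2 calls and turned 1, UQCRC2 between Banhasasim-tang and Bojungikgi-tang at 500 µg/mL (-0.02 against 0.15 ± 0.04), DESeq2 ended 1, the 2 groups alone 17, relative log expression factors 0, and leaving out 1 library 66 of the 1729 values it gave. Correlations between formulas over genes of at least 5 CPM in enough libraries were 0.84 and 0.62 for Bojungikgi-tang and Sayeok-tang (500 µg/mL against vehicle, then against 20), 0.69 and 0.67 for Sayeok-tang and Banhasasim-tang, and 0.34 for Bojungikgi-tang and Banhasasim-tang between doses. Over all tested genes, where the same correlations were 0.72 and 0.20, 0.62 and 0.31, and 0.50 and 0.15, leaving out single libraries gave 0.67 to 0.78 and 0.16 to 0.22 for Bojungikgi-tang and Sayeok-tang, 0.49 to 0.67 and 0.26 to 0.29 for Sayeok-tang and Banhasasim-tang, and 0.39 to 0.58 and 0.10 to 0.16 for Bojungikgi-tang and Banhasasim-tang. Except for the stricter thresholds named, the cause of these differences between settings was not tested. At the depth, number of libraries and spread of these data together, simulated 1.5-fold changes of genes with a mean of at least 1 CPM were recovered in 76 to 94% of cases. With replicate numbers as a block 6965, 4554 and 5390 genes passed for Bojungikgi-tang at 500, 100 and 20 µg/mL, 7717, 5940 and 5212 for Sayeok-tang and 9995, 5387 and 3371 for Banhasasim-tang, 3186, 4151 and 8724 between doses, and 2597, 9336 and 8115 between formulas, the block ending 2 calls of named genes and 0 of lists. The numbers did not pair samples, with correlations of same-numbered libraries from -0.06 to 0.043 and 7 of 27 libraries closest to their own number.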

Other observations

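Tests chosen only after the result was seen were the GC and length correction, the thinning, the 18S covariate, those of a handling batch of the vehicle libraries, of a label set effect and a dose effect on the mitochondrial ribosomal RNAs, and the list tests that hold no vehicle library. At 500 µg/mL against vehicle, nuclear genes of oxidative phosphorylation had 1 higher and 5 lower of 26 under Bojungikgi-tang, 2 and 5 under Sayeok-tang and 4 and 4 under Banhasasim-tang, and 1 and 4, 2 and 4, and 4 and 4 adjusted over the list alone (camera adjusted p = 0.592, 0.671 and 0.857). Hypoxia targets had 6 higher and 10 lower of 21, 7 and 8, and 7 and 10, with the same counts adjusted over the list alone (adjusted p = 0.479, 0.435 and 0.386). Between the doses of Banhasasim-tang the metastasis suppressor NDRG1 stood at 2.04 ± 0.06 and VEGFA at 0.90 ± 0.06, and EGLN3 at -2.40 ± 0.14 and PFKFB4, a regulator of glycolysis, at -1.07 ± 0.08. Fatty acid synthesis genes had 5 higher and 7 lower of 14, 6 and 5, and 4 and 9, and 5 and 8, 6 and 6, and 4 and 9 adjusted over the list alone (adjusted p = 0.325, 0.394 and 0.124), whereas Bojungikgi-tang lay below Sayeok-tang in 9 members and above in 1, the counts adjusted over the list alone being the same (adjusted p = 2.31e-05, and adjusted p = 0.0524 with an estimated correlation). LXR targets had 4 higher and 1 lower of 10 under Bojungikgi-tang, also adjusted over the list alone (adjusted p = 0.0412, and adjusted p = 0.165 with an estimated correlation), 5 and 2 under Sayeok-tang and 6 and 2 under Banhasasim-tang, 6 and 2 in each adjusted over the list alone (adjusted p = 0.176 and 0.156), and the lipid exporter ABCA1 rose by 1.15 ± 0.09 under Banhasasim-tang. Metallothionein and zinc genes had 2 higher and 1 lower of 8 under each formula, and 2 and 1, 3 and 1, and 2 and 1 adjusted over the list alone (adjusted p = 0.983, 0.179 and 0.947). Under Bojungikgi-tang and Banhasasim-tang their mean fold changes were 0.31 and 0.58, although the test pointed lower. The test weighs each change against its spread before the list is compared with other genes. Among the members SLC30A2 was near the floor, at 0.622 CPM under Banhasasim-tang against 0.0439 in vehicle. Matrix proteases had 3 higher and 6 lower of 15, 2 and 6, and 2 and 1, and 3 and 6, 2 and 6, and 2 and 0 adjusted over the list alone (adjusted p = 0.246, 0.096 and 0.621).

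Interferon response genes had 10 higher and 0 lower of 23 under Bojungikgi-tang at 500 µg/mL, and 11 and 0 adjusted over the list alone (adjusted p = 0.00287, and adjusted p = 0.382 with an estimated correlation), and 8 higher and 3 lower under Sayeok-tang and 7 and 8 under Banhasasim-tang, 9 and 3, and 7 and 8 adjusted over the list alone, where the list was not called (adjusted p = 0.268 and 0.616). Messenger RNAs encoded in mitochondria rose in 11 of 13 under Bojungikgi-tang, also adjusted over the list alone (adjusted p = 0.000318, and adjusted p = 0.392 with an estimated correlation), and in 12 of 13 at 20 µg/mL, also adjusted over the list alone (adjusted p = 2.35e-06, and adjusted p = 0.292 with an estimated correlation), with no call between those doses (adjusted p = 0.658). Cytosolic ribosomal protein genes rose in 12 of 26 under Banhasasim-tang, also adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.719 with an estimated correlation, or 0.0773 with library size only). Epithelial and liver markers fell in 4 of 5 under Bojungikgi-tang, also adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.183 with an estimated correlation), the keratins KRT18 and KRT7 among them, and in 3 of 5 against 20 µg/mL, also adjusted over the list alone (adjusted p = 4.72e-06, and adjusted p = 0.013 with an estimated correlation). Against vehicle, the call of KRT8 (-0.25 ± 0.1) was lost on leaving out any single library of either group and with library size only. That of KRT19, at 0.282 against 0.549 CPM, was lost with DESeq2 and on leaving out some of the libraries. Neuron markers fell in 4 of 9 under Sayeok-tang, also adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.0711 with an estimated correlation). Oligodendrocyte markers had 0 higher and 3 lower of 6, 0 and 3, and 2 and 4 under the 3 formulas, with the same counts adjusted over the list alone (adjusted p = 0.0971, 0.096 and 0.291), with a median of -0.33 and a mean of 0.09 under Banhasasim-tang, and the progenitor receptor PDGFRA stood at -1.47 ± 0.08 under Banhasasim-tang.

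The 20 µg/mL libraries of Bojungikgi-tang and Sayeok-tang differed from vehicle in 5139 and 4973 genes, with longer and GC-poorer genes lower. Correction for GC content and length gave counts of calls that were 72.7 and 77% of these, and thinning to the shallowest library 93.3 and 92.7%, which argues against either as the whole source. With 18S level as a covariate the counts were 50.6 and 59.3% of these. Since 18S level itself differed between vehicle and treated libraries, this covariate can remove calls of any source. Whether a difference in carried-over structural RNA accounts for part therefore stays open. Since 0 treated libraries lie in the vehicle label set, a handling batch and an effect of the extracts, or of their solvent, cannot be told apart. A response common to the extracts that grows with dose would raise the correlation across genes of separate dose steps. This correlation was 0.03 between 20 µg/mL of Bojungikgi-tang over vehicle and 500 over 20 µg/mL of Sayeok-tang, and -0.08 with the formulas exchanged. Such correlations can depend on the genes included. For 500 over 20 µg/mL, these formulas correlated at 0.2 over all tested genes and 0.63 over genes with a mean of at least 5 CPM. The low values therefore cannot decide whether a common response grows with dose, and this stays open. A response already complete at the lowest dose stays open too.

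The mitochondrial ribosomal RNA MT-RNR1 was higher by 3.23 ± 0.08 in the 6 Banhasasim-tang libraries than in the 18 of Bojungikgi-tang and Sayeok-tang, and MT-RNR2 by 2.09 ± 0.03. Carried-over ribosomal RNA in general is argued against by the nuclear 18S loci, with a median of -0.79 (SE 0.49 over 3 near-identical loci), more mitochondrial transcripts by the 13 mitochondrial messenger RNAs, with a mean of -0.18 ± 0.08, and the scaling by 3.11 with library size only. A shared label set is argued against by Yijung-tang of the same set, whose highest library held 1280 CPM of MT-RNR1 where the lowest of Banhasasim-tang held 4250. From 20 to 100 µg/mL of Banhasasim-tang MT-RNR1 rose by 1.81 ± 0.20, consistent with an effect of the extract, but from 100 to 500 µg/mL it stood at 16900 and 16800 CPM and MT-RNR2 at 89100 and 66800 CPM, so the values did not rise with dose throughout. Averaged over doses, MT-ND1 and MT-ND2, which lie next to the ribosomal genes, were higher than under Bojungikgi-tang and Sayeok-tang by 0.49 ± 0.11 and 0.33 ± 0.11. At 20, 100 and 500 µg/mL of Banhasasim-tang, MT-ND1 stood at 7280, 5480 and 4240 CPM and MT-ND2 at 6290, 4650 and 3910. At 500 µg/mL of Bojungikgi-tang and Sayeok-tang, MT-ND1 stood at 4180 and 3960 CPM and MT-ND2 at 4170 and 3910. Their excess was thus largest at 20 µg/mL, where MT-RNR1 was lowest for this formula (4820 CPM). Whether library preparation of this formula's samples contributed stays open.

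Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. Fitted to the 2 groups alone, the real split gave 8378, 5474 and 2758 genes for Bojungikgi-tang at 500, 100 and 20 µg/mL against vehicle and 8141, 5654 and 5417 for Sayeok-tang, with 0 in the highest other split of each. Between doses it gave 1336 against 3 for Bojungikgi-tang and 3884 against 0 for Sayeok-tang, and 3575 against 1 between these formulas at 500 µg/mL. For each of these 9 comparisons 1 split of 10, the real one, gave as many genes.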
